A study of Caenorhabditis elegans with 2 samples.

How the data were processed

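CEH-22 ChIP-seq of whole late *C. elegans* embryos, mixed sex, was represented by 2 biological replicates, numbered as in the labels, which form 1 group. Per the labels the chromatin was sonicated, the strain carried a transgene with C-terminally GFP and FLAG tagged CEH-22, and the antibody is given as CEH-22, with no statement of whether it recognised the tag. The control samples named in the labels were not analysed here. Signal tracks were not used here.

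Per the deposited file listing, each replicate's relaxed list (peaks and background) was made from the alignments of that replicate and a control, the pooled relaxed list from the alignments of both replicates and a control, and the thresholded list by IDR, a test of reproducibility between ranked lists, from the pooled and both replicate lists. Each list was given on builds ce10 and ce11. The peak caller, the aligner and their versions are not given in the sources used here. The signal value of each region is a score that the authors' peak caller gave, on a scale not stated. It was used to rank and select regions within a list and to correlate ranks between lists, and, within a list, described by medians, by the value of a neighbouring region relative to a peak, and by the spread of its logarithm. The deposited −log10 q of each region was between 1.35 and 1.82 in the thresholded list and was not used in any test. On ce11 the thresholded list was identical to the 285 pooled regions with the largest signal value, and 283 of its summits lay within 2 bp of the region's midpoint. The median width equalled the largest (344 bp in the thresholded and pooled lists and in replicate 2, 350 bp in replicate 1), so widths were not compared. Read depth is unknown, and intervals on shares cover counting error over peaks only.

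Coordinates are those of ce11, which is assembly WBcel235, written 1-based. Gene models came from the Ensembl annotation and sequence and mitochondrial gene names from RefSeq, both of that assembly. A gene's 5' end was the outer end of its annotated span. A summit was assigned to every protein-coding gene whose 5' end placed it between 1000 bp upstream and 200 bp downstream, otherwise to the nearest protein-coding 5' end within 5000 bp, otherwise to none. This assigned 114 peaks by the promoter window and 133 by the nearest 5' end, and left 38 without a gene. A gene of a list had a region if any region was assigned to it.

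Replicate overlap was the share of the 285 strongest regions of replicate 1 with a summit within 200 bp of one of the 285 strongest of replicate 2. That share and the promoter share were tested two-sided against 100000 circular shifts, with 1 random offset per chromosome. Replicate signals were compared by Spearman's rho over peaks with 100000 permutations. Chromosome shares were tested with two-sided exact binomial tests against the pooled relaxed list. Gene lists, sequences, annotation classes and non-coding genes were tested with two-sided Fisher's exact tests against relaxed regions, or genes with only relaxed regions. Families of tests (7 chromosomes, 12 gene lists, 4 annotation classes, 4 non-coding types, 3 control sequences, 8192 7-mers) were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Sequence windows reached 100 bp to each side of the summit. Background windows were drawn without replacement from pooled regions that overlapped no thresholded peak, 10 per peak in GC bins of 5 percentage points, or all of a bin where fewer existed, which gave 2773 windows with a mean GC content of 47.7% against 48.4% in the peaks. The two-sided rank test of gene lists used 10000 random gene sets, drawn from all genes or matched on the number of regions per gene, with 6 or more counted together.

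The gene lists (pharyngeal muscle, other pharynx, pharyngeal transcription factors, body wall muscle, shared contractile, intestine, epidermis, collagens, neurons, ribosomal proteins, homeobox *ceh*, Wnt and distal tip cell genes), the main tests, the alternatives and the rule for named genes were fixed before the data were examined. *ceh-22* belongs to 4 of the lists. Named genes were those assigned to the 20 strongest peaks, every list gene with a thresholded peak (the 3 strongest for collagens, ribosomal proteins and *ceh* genes), and *ceh-22* and *unc-119*. *myo-2*, *egl-30*, *F53E2.2*, *ifet-1*, *gar-3*, *lev-11*, *col-72*, *ajm-1*, *lit-1* and the *sls-2* genes were named after their values were seen.

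Alternatives were other overlap criteria and list sizes, other promoter windows, window widths and backgrounds, other gene universes and assignments, the 142 strongest peaks, the ce10 lists, and the 285 strongest regions of 1 replicate alone with that replicate's relaxed list as background. For ce10 shifts, the end of the last region on a chromosome stood for its length, since ce10 chromosome lengths were not used here. Leaving out the mitochondrial genome, the rank test, the assignment of a peak also to genes whose span held its summit, the NK-2 tests outside promoter windows and of promoter against other peaks, the annotation classes, the split of non-coding genes by type, the GC content of the windows, the adjustment over control sequences, the correlations with pooled values and over all regions, the spread of log signal values (ratios with percentile bootstrap intervals from 1000 draws), and the GAGAGAGA repeat were added after seeing the data. The annotation classes were run with and without the mitochondrial genome, and the non-coding types under the main setting only.

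The functions were tested on simulated data. With 40% of 285 positions shared between simulated replicates, 40.4% were recovered. With 20% of 285 positions placed in promoters, the promoter share was 35.4% for 37.5% expected. TCAAGTG planted in 10% of 285 windows gave a share of 14.0% for 14.4% expected, and it ranked 1 of all 7-mers with no other past the threshold. Those windows and their background came from random genomic positions without GC matching. The simulation therefore did not test how 7-mers behave against relaxed regions. With 5 of the 17 shared contractile genes added to the genes with a peak, that list passed the threshold in 100 of 100 simulated sets. In the data 3 of 17 had a peak, so power at that effect was not shown. Of 100 sets without added genes, 1 had a list past the threshold. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.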

Results

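CEH-22 is a homeodomain transcription factor of the NK-2 class, best known as an activator of muscle genes in the pharynx, the feeding organ of the nematode *Caenorhabditis elegans*. Its chromatin binding was profiled by ChIP-seq (immunoprecipitation of sonicated chromatin followed by sequencing) in whole late embryos of a transgenic line that carries CEH-22 with a GFP and FLAG tag at its C-terminus. There was 1 group of 2 biological replicates, so the design allowed a description of where peaks lay and how well the replicates matched, and no contrast of conditions. On genome build ce11 the thresholded list held 285 peaks, the pooled relaxed list 19644 regions and each replicate's relaxed list 30000 regions. Read numbers were not part of these lists, so the depth behind each peak is unknown. The signal values below are the authors' values per peak on a scale not stated, and were used to rank, select and describe peaks within a list.

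The strongest nuclear peak lay in the gene for CEH-22 itself, which the transgene also carries. A contribution of extra gene copies to its signal could not be told apart from binding. This peak (chromosome V, 10672597 to 10672940, ce11) had a pooled signal value of 214, and it ranked 2 in the pooled list and 2 in each replicate, with values of 114 in both. Its summit at 10672769 fell in *ceh-22* (V, 10671918 to 10675769, plus strand), in the coding part of the exon that is exon 1 of its annotated transcripts a and d. It lay 851 bp downstream of the gene's 5' end and 135 bp downstream of the start of that coding part. An NK-2 site, TCAAGTG, was centred 27 bp downstream of the summit (V, 10672793 to 10672799, plus strand). In its context the sequence read TTCATCGGCTTCAAGTGCATCAGCGGC (10672783 to 10672809). Another thresholded peak at the gene's 5' end (10671780 to 10672123) had a signal value of 49.7 and rank 73. *unc-119*, the gene that the labels give as mutated in this strain (III, 10902641 to 10908935), had no thresholded peak, and its strongest pooled region ranked 12669 with a value of 11.1.

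**Figure D1:**
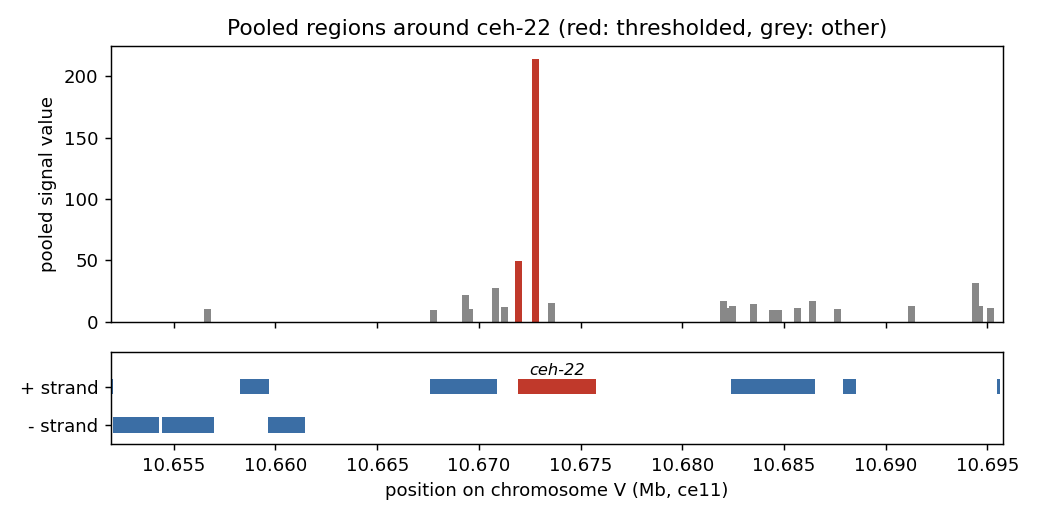
Pooled regions within 20 kb of *ceh-22* on chromosome V (x axis, Mb, ce11) with their signal value (y axis, as deposited), above the annotated protein-coding genes by strand. Each bar is 1 region, red if it passed the threshold. The peak in *ceh-22* reaches 214 and the peak at the gene's 5' end 49.7, while the next strongest region shown has a value of 31.4.

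The remaining strong peaks fell on the mitochondrial genome and near genes with varied functions. Of the 20 strongest peaks, 6 were mitochondrial, with summits in the genes ND5, COX1, COX3, ND4 and ATP6, which encode respiratory chain and ATP synthase subunits. The ND5 peak (12402 to 12526) was the strongest of all, at 454, and ranked 1 in both replicates. COX1 held 2 of them, at 137 and 126, and the weaker of these ranked 631 in replicate 1 and 3 in replicate 2. The stronger COX1 peak ranked 33 and 4 in the same order, and the COX3 peak 354 and 5. The ND4 peak ranked 4 and 8, and the ATP6 peak 22 and 13. Whether the mitochondrial peaks reflect CEH-22 binding was not tested. Among nuclear peaks, rank 3 lay 48 bp upstream of *T09B4.3* (I, 6175033 to 6175193, 154). Rank 7 lay 74 bp upstream of *atx-2*, the ataxin-2 orthologue, and 764 bp upstream of *ecps-1* (III, 10461143 to 10461486, 118). Rank 9 lay in an intron of the cuticlin-like gene *cutl-18*, close to a small nucleolar RNA (snoRNA) gene (V, 11314028 to 11314371, 95.6). Rank 10 lay 64 bp upstream of *tasp-1* and 721 bp upstream of *K01G5.10* (III, 10759071 to 10759414, 92.8). Rank 12 was assigned to *C53H9.4*, with its summit in an untranslated exon of *egl-30*, a G protein alpha subunit gene. Ranks 14, 16, 17, 18 and 19 were assigned to *hrg-5*, *W02H3.3*, *F55C5.17*, *ain-1* (a component of microRNA silencing complexes) and *sup-37*, with signal values from 84.5 down to 75.7. The rank 17 peak lay in an intron of another gene, close to snoRNA genes. The *ain-1* peak (X, 16612363 to 16612706) ranked 14 in replicate 1 and 4692 in replicate 2. Ranks 13, 15 and 20 had no protein-coding 5' end within 5000 bp in the annotation.

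The replicates shared many of their strongest regions. Of the 285 strongest regions of replicate 1, 109 had a summit within 200 bp of 1 of the 285 strongest of replicate 2 (38.2%, 95% Wilson interval 32.8 to 44.0), against a mean of 0.846% under circular shifts along each chromosome. The two-sided permutation p = 2e-05 was the smallest that 100000 shifts can give. Of the 285 thresholded peaks, 277 had a region in both relaxed lists, 106 were among the 285 strongest of both replicates and 20 among those of neither. Across those 277 peaks no correlation of the replicates' signal values was detected (Spearman rho 0.0463, two-sided permutation p = 0.442 over peaks, which are not independent replicates). The thresholded peaks are those with the largest pooled value, made from both replicates. Over all 7457 replicate 1 regions with a replicate 2 summit within 200 bp, rho was 0.231. The pooled value correlated with that of replicate 1 (rho 0.582 over 279 peaks) and with that of replicate 2 (rho 0.679 over 283 peaks), which is built in, since it was made from the reads of both.

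**Figure D2:**
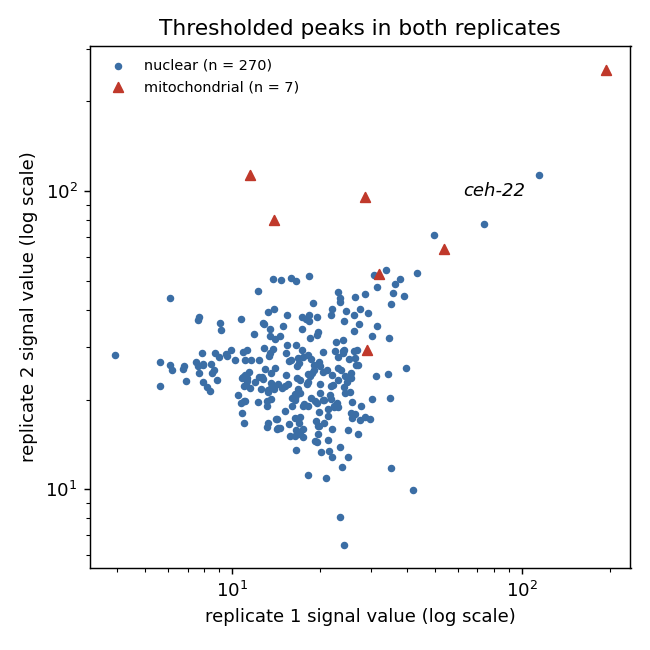
Signal value of each thresholded peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), for the 277 peaks with a region in both lists. Points are nuclear peaks and triangles mitochondrial ones. The *ceh-22* peak lies at 114 on both axes, and the bulk of the points forms a cloud without a visible slope, with a rho of 0.0463. The peaks shown are those with the largest pooled value, which was made from both replicates.

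Peaks lay near promoters and in intergenic DNA and rarely in coding exons. In all, 114 of 285 summits (40%, Wilson interval 34.5 to 45.8) were between 1000 bp upstream and 200 bp downstream of a protein-coding 5' end, against 22.4% under circular shifts (two-sided permutation p = 2e-05). Relaxed regions that did not overlap the peaks were at 23.7%. Summits in intergenic DNA made up 65.3% of the peaks and 33.0% of relaxed regions (odds ratio 3.81, 95% interval 2.96 to 4.92, Fisher's exact test, adjusted p = 1.64e-27). Coding exons held 15 summits, or 5.26%, against 31% of relaxed regions (odds ratio 0.123, interval 0.0680 to 0.207, Fisher's exact test, adjusted p = 1.83e-26). Of these, 8 were mitochondrial, and without the mitochondrial genome 7 of 277 summits remained (2.53%, odds ratio 0.0576, interval 0.0229 to 0.120). Untranslated exons were also under-represented, with 2.11% against 5.15% (Fisher's exact test, adjusted p = 0.0265). Introns held 27.4% of peaks and 30.8% of relaxed regions, a difference that did not pass the test (Fisher's exact test, adjusted p = 0.244).

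Chromosome shares differed from the pooled relaxed list for the mitochondrial genome, chromosome V and the X chromosome. The mitochondrial genome held 8 peaks (2.81%, expected 0.0509%, exact binomial test, adjusted p = 2.72e-11). All 8 were among the 55 strongest, their median signal value was 115 against 40.1 for nuclear peaks, and 0 of their windows held an NK-2 site. With only 8 windows, 0 is also likely at the 5.19% share of the GC-matched relaxed windows, so it shows no difference from them. Chromosome V was under-represented with 33 peaks (11.6%, expected 18.6%, exact binomial test, adjusted p = 0.00606). The X chromosome held 71 peaks (24.9%, Wilson interval 20.2 to 30.2, expected 18.8%, exact binomial test, adjusted p = 0.0228). With the 285 strongest regions of a single replicate the X share was 23.9% in replicate 1 and 21.4% in replicate 2, neither past the threshold (exact binomial test, adjusted p = 0.108 and 0.446). The shares of chromosomes I to IV did not pass the test, with adjusted exact p between 0.569 and 0.751.

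Short non-coding RNA genes were frequent neighbours of the peaks. These genes were compared because short, highly transcribed genes are known sites of non-specific ChIP signal. Whether the peaks near them reflect CEH-22 binding was not tested. The relaxed regions were not matched on GC content here (mean of 39.8% against 48.4% in the peaks). A tRNA, snRNA, snoRNA or rRNA gene lay within 200 bp of 45 summits (15.8%, Wilson interval 12 to 20.5) and of 1.74% of relaxed regions (odds ratio 10.6, interval 7.37 to 14.9, Fisher's exact test, p = 7.96e-28). By type, snoRNA genes were near 25 peaks (8.77% against 0.512%, odds ratio 18.7, Fisher's exact test, adjusted p = 4.60e-21). Genes for tRNA were near 16 peaks (odds ratio 5.29, Fisher's exact test, adjusted p = 5.87e-07), and those for snRNA near 4, including 3 *sls-2* genes, which encode spliced leader RNAs (odds ratio 11.4, Fisher's exact test, adjusted p = 0.000906). No rRNA gene lay near a peak, with an upper Wilson limit of 1.33%. Only 2 of 19321 relaxed regions lay near an rRNA gene (0.0104%), so 0 peaks are likely at that share too and show no difference.

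Muscle, ribosomal and other gene lists were compared to ask whether peaks gathered at genes of the tissue in which CEH-22 is known to act. A peak counted for a gene by its distance from the 5' end, so a peak deep inside a gene could count for another gene or for none. A thresholded peak was assigned to 266 protein-coding genes among the 10835 with a pooled region. None of the 12 lists passed the adjusted threshold, and 3 had an unadjusted p under 0.05. Of the pharyngeal muscle genes, 2 of 12 had a peak (odds ratio 8.0, 95% interval 0.848 to 37.8, Fisher's exact test, p = 0.0337, adjusted p = 0.135). Without peaks within 40 kb of *ceh-22* and *unc-119* the odds ratio was 3.64 (Fisher's exact test, p = 0.257, adjusted p = 1). *ceh-22* stayed among the 12 genes there and counted as without a peak, so part of the fall is built in. The genes were *ceh-22* and *tnt-4*, a troponin T gene, whose peak lay in an intron 400 bp downstream of the 5' end (V, 1992346 to 1992689, 39.9). *myo-2*, the pharyngeal myosin heavy chain gene, had a region 254 bp upstream of its 5' end that ranked 949 in the pooled list and did not reach the threshold. Of the contractile genes shared between muscles, 3 of 17 had a peak (odds ratio 8.60, interval 1.57 to 31.1, Fisher's exact test, p = 0.00771, adjusted p = 0.0763). The peak assigned to the actin gene *act-1* lay in intergenic DNA 2769 bp downstream of its 5' end (V, 11083649 to 11083992, 45.2). That of *act-4* lay in an intron with an NK-2 site (X, 4961612 to 4961955, 37.7). The windows of the *tnt-4*, *act-1* and *unc-60* peaks held no NK-2 site. The peak of *unc-60*, which encodes ADF/cofilin, lay 363 bp upstream of it and of *F53E2.2* (V, 1474551 to 1474894, 32.6), with no replicate 1 summit within 200 bp. Of the ribosomal protein genes, 5 of 57 had a peak (odds ratio 3.87, interval 1.20 to 9.75, Fisher's exact test, p = 0.0127, adjusted p = 0.0763). The strongest were *rpl-3* (311 bp upstream, III, 3867371 to 3867714, 59.8), *rpl-35* (453 bp upstream, III, 7854509 to 7854852, 58.6) and *rps-1* (269 bp upstream, III, 4475477 to 4475820, 53.5), the last also 499 bp upstream of *ifet-1*.

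Peaks were assigned to few or no genes of the other lists. *ceh-22* was the single gene with an assigned peak among 12 pharyngeal transcription factors, 36 homeobox *ceh* genes and 13 Wnt and distal tip cell genes, and *col-177* the single one among 88 collagens (Fisher's exact test, adjusted p between 0.663 and 1). None of 10 other pharyngeal genes, 17 body wall muscle genes, 10 intestinal, 23 epidermal or 18 neuronal genes had an assigned peak, and the upper 95% limits of their odds ratios lay between 6.94 and 17.8. Introns of 5 list genes held a peak that was not assigned to them. These were *gar-3* (pharyngeal muscle, V, 14574075 to 14574418, 35.8, with 2 NK-2 sites), *lev-11* (shared contractile, I, 14625667 to 14626010, 46.7), *col-72* (collagens, II, 3521362 to 3521705, 43.6), *ajm-1* (epidermis, X, 9102150 to 9102493, 36.5) and *lit-1* (Wnt, III, 13718495 to 13718838, 32.6). Only the *gar-3* window held an NK-2 site. The *col-72* peak lay close to a tRNA gene, and 266 bp upstream of the gene to which it was assigned. With genes whose span held a summit also counted, an alternative chosen after seeing the data, the pharyngeal muscle list (3 of 12, odds ratio 12.9, interval 2.23 to 51.8) and the shared contractile list (4 of 18, odds ratio 11.0, interval 2.63 to 35.4) passed the threshold (Fisher's exact test, adjusted p = 0.0183 and 0.0115). The pharyngeal muscle genes counted were *ceh-22*, *tnt-4* and *gar-3*, and this setting was not run without the *ceh-22* locus. With circular shifts as the null, the ribosomal list (5 genes against a mean of 0.516) and the shared contractile list (3 against 0.304) passed the threshold (permutation, adjusted p = 0.0096 and 0.0276). The shifts did not keep the peaks' preference for promoters (40% observed against 22.4% under shifts), which can favour lists with promoter peaks. With only promoter windows counted, 5 of 47 ribosomal and 1 of 10 shared contractile genes had a peak. Neither list passed there (Fisher's exact test, adjusted p = 0.157 and 0.635).

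The lists were also compared by the rank of each gene's strongest pooled region, a test chosen after the peaks had been seen. The median pharyngeal muscle gene stood at 11.8% of genes counted from the strongest, against a median of 39.3% for random genes matched on their number of regions (permutation, adjusted p = 0.016). Body wall muscle genes stood at 16.6% (matched median 42.3%, permutation, adjusted p = 0.016) although none had a thresholded peak. Ribosomal protein genes stood at 22.5% (matched median 50.2%, permutation, adjusted p = 0.0024). Shared contractile genes stood at 12.8% and pharyngeal transcription factors at 18.5%, past the threshold against all genes (permutation, adjusted p = 0.0012 and 0.0192) and not against matched genes (permutation, adjusted p = 0.102 and 0.213). The other 7 lists passed neither comparison.

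**Figure D3:**
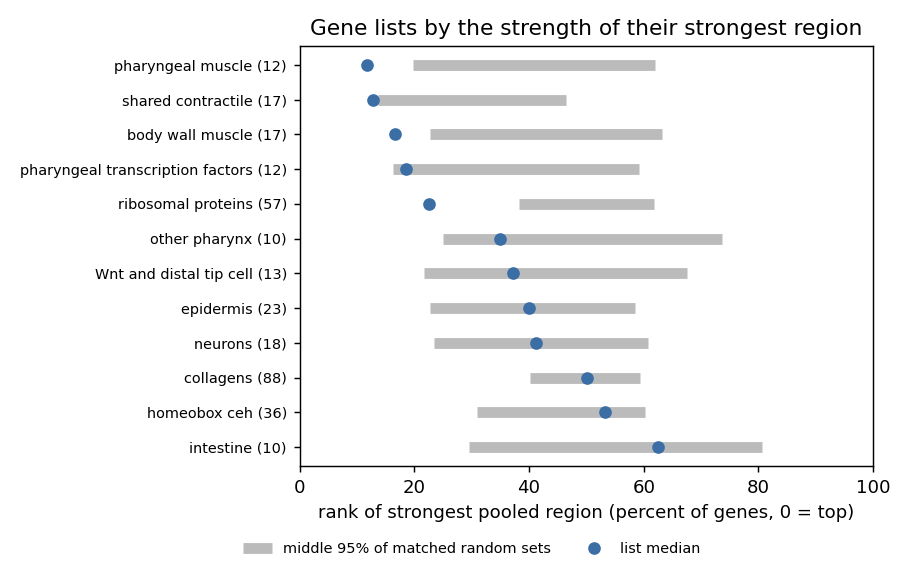
Median rank of each list's genes by their strongest pooled region (x axis, percent of the 10835 genes, 0 the strongest), with the middle 95% of random gene sets matched on the number of regions per gene in grey. Numbers in brackets are genes in the list. Pharyngeal muscle (11.8%), shared contractile (12.8%), body wall muscle (16.6%) and ribosomal protein genes (22.5%) lie below their grey ranges, of which the shared contractile list did not pass after adjustment.

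The NK-2 site TYAAGTG was enriched under the peaks. It occurred within 100 bp of 32 of 285 summits (11.2%, Wilson interval 8.07 to 15.4) and in 5.19% of 2773 GC-matched relaxed windows (odds ratio 2.31, 95% interval 1.49 to 3.49, Fisher's exact test, p = 0.000143). Of the forms of the site, TCAAGTG was in 30 windows (10.5% against 4.08%, odds ratio 2.77, Fisher's exact test, adjusted p = 0.00173, rank 55 of 8192 7-mers), and TTAAGTG in 2 (0.702% against 1.19%, rank 6186). Among peaks with a summit in a promoter window the site was in 5 of 114, an odds ratio of 1.10 against matched promoter windows (interval 0.332 to 2.90, Fisher's exact test, p = 0.800). Outside promoter windows it was in 27 of 171 peaks, or 15.8%, against 5.60% (odds ratio 3.16, interval 1.91 to 5.08, Fisher's exact test, p = 5.61e-06). The difference in the site's share between promoter and other peaks passed a test of its own (odds ratio 0.245, interval 0.0715 to 0.676, Fisher's exact test, p = 0.00348). The tests outside promoter windows and of that difference were chosen after seeing the data. The reversed control GTGAAYT was in 1.75% of peaks and 3.82% of matched windows (Fisher's exact test, adjusted p = 0.141), and the GATA site TGATAA in 7.72% and 9.70% (Fisher's exact test, adjusted p = 0.339). The forkhead site TRTTKRY was in 42.8% and 35.3% (odds ratio 1.37, Fisher's exact test, adjusted p = 0.0410). That call was lost in replicate 1 alone, in the 142 strongest peaks and in promoter windows (odds ratios 1.35, 1.49 and 1.26, Fisher's exact test, adjusted p = 0.0528, 0.0850 and 0.452), and the odds ratio was 0.962 without GC matching and 0.754 against flanking windows.

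**Figure D4:**
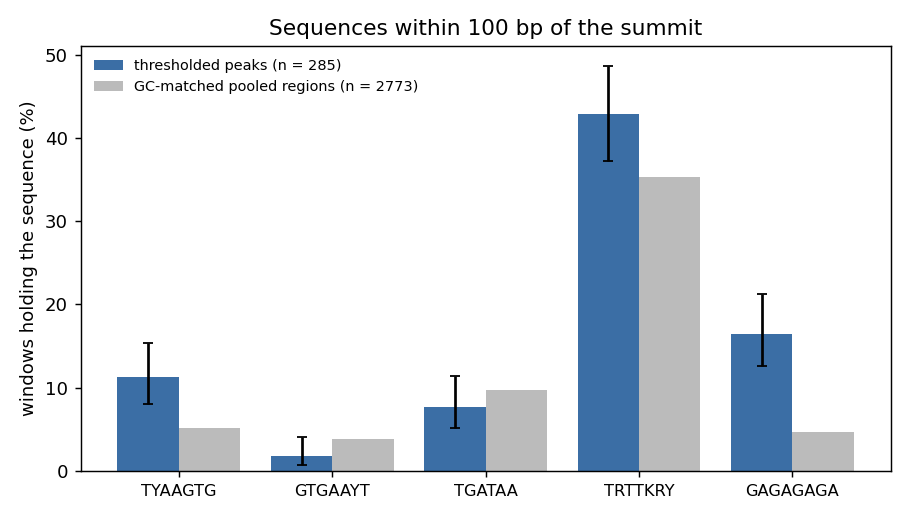
Share of 201 bp windows around the summit that hold each sequence on either strand (y axis, percent), for the 285 thresholded peaks (blue, with 95% Wilson intervals) and the 2773 GC-matched relaxed windows (grey). TYAAGTG (11.2% against 5.19%) and GAGAGAGA (16.5% against 4.72%) stand above the matched windows. GAGAGAGA was chosen after seeing the data.

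Without a sequence chosen in advance, GA repeats ranked first among the 7-mers. Of 8192 7-mers, 157 were more frequent and 29 less frequent in the peaks (Fisher's exact test with Benjamini-Hochberg adjustment). CTCTCTC ranked 1, in 29.5% of peaks and 9.56% of matched windows (odds ratio 3.96, Fisher's exact test, adjusted p = 8.70e-15), and AGAGAGA ranked 2 (27% against 9.74%, odds ratio 3.43). Of the first 20, 5 held only purines on 1 strand, and GCGCGCA at rank 7 had an odds ratio of 5.08. In the 142 strongest peaks GTGTGTA ranked 1 (odds ratio 5.37, Fisher's exact test, adjusted p = 0.000312) and CTCTCTC 3 (odds ratio 3.30, Fisher's exact test, adjusted p = 0.000566). The peaks' windows had a mean GC content of 48.4% ± 6.53 (SD, n = 285 windows) against 39.8% ± 6.82 for other pooled regions (SD, n = 19321 windows).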

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

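Leaving out the mitochondrial genome, the rank tests of gene lists, the count of genes whose span held a summit and the test outside promoter windows were chosen after seeing the data. Replicate overlap (24.8 to 40.7%), promoter share (26.7 to 53.7%) and non-coding gene overlap (odds ratio 6.33 to 14) kept their direction and stayed past the threshold under every alternative run, and the ce10 list held 283 peaks. The replicate correlation across thresholded peaks passed in no alternative, and its rho of 0.0463 became -0.0261 in the 142 strongest peaks. The cause of that change was not tested. Over all regions matched between the replicates, not only thresholded peaks, rho was 0.231 and passed (permutation p = 0.000999). Chromosomes past the threshold, 3 in the main test, were 2 in each single replicate and without the mitochondrial genome, and 3 otherwise. The X share fell from 24.9% to between 21.4 and 23.9% in single replicates and no longer passed; the cause was not tested. The NK-2 odds ratio was 1.10 in promoter windows, where it did not pass, and 1.56 to 3.67 otherwise; the cause was not tested. The count of gene lists past the threshold, 0 in the main test, was 1 in each single replicate (shared contractile), 1 with the nearest 5' end at any distance (pharyngeal muscle), 2 with all genes as the universe, 2 with circular shifts as the null, 2 with genes whose span held a summit also counted (pharyngeal muscle and shared contractile), 5 by rank and 3 by rank with matched genes; the cause was not tested. Odds ratios of lists that did not pass under the setting in question also turned direction. Body wall muscle had odds ratios of 2.42 to 2.71 in single replicates, and collagens 1.00 and neurons 2.13 in replicate 1 alone. Homeobox *ceh* genes had 0.945 with the nearest 5' end at any distance and 0.888 with gene spans counted, and epidermal genes 1.66 with spans, through *ajm-1*. The cause was not tested. Without peaks within 40 kb of *ceh-22* and *unc-119*, pharyngeal transcription factors, *ceh* genes and Wnt genes had an odds ratio of 0, since *ceh-22* was their one gene with a peak, and pharyngeal muscle genes 3.64 instead of 8.0. *ceh-22* stayed in these lists as a gene without a peak, so these falls are at least in part built in. Every setting under which pharyngeal muscle genes passed counted *ceh-22*, and none was run without its locus. The share on chromosome II, 15.8%, lay on the other side of the share expected from its length. The forkhead odds ratio of 1.37 became 0.754 against flanking windows and 0.962 without GC matching, where the background's mean GC content was 35.8% and 39.8% instead of 47.7%; the cause was not tested. TTAAGTG had odds ratios of 0.796 to 1.29 in single replicates, and the cause was not tested. Among the values for single lists, annotation classes, single sequences other than the NK-2 site as a whole, and single chromosomes other than X, 160 alternatives kept direction and side of the threshold, 15 came past it in the main direction, 3 fell short of it and 14 turned direction. The 186 7-mers past the threshold became 42 in the 142 strongest peaks, which are fewer windows, 121 to 221 in single replicates, 75 within 50 bp and 528 within 250 bp of the summit; the cause was not tested. The first of them was GTGTGTA in the 142 strongest peaks, AGAGAGA within 50 bp and CTCTCTC otherwise. With unknown read depth, differences between the replicates at single peaks could not be tested.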

Other observations

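The GAGAGAGA repeat, the single-copy check, the locus tests, the correlation over all regions and the comparison of signal spreads were chosen only after the peaks had been seen, and the locus tests also after the regions around *ceh-22* had been seen. The design gives no other group, so no biological explanation was tested for any pattern here.

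GAGAGAGA lay within 100 bp of 47 of 285 summits (16.5%, Wilson interval 12.6 to 21.2). By chromosome it was in 27.5% of the 51 peaks on I, 24.4% of the 45 on II, 16.2% of the 37 on III, 15% of the 40 on IV, 12.1% of the 33 on V and 8.45% of the 71 on the X chromosome. GC-matched relaxed windows had shares of 5.24%, 2.78%, 5.33%, 6.08%, 3.66% and 5.39% in the same order. The X chromosome was set against the autosomes because its share was the lowest (Fisher's exact test, two-sided, p = 0.0278, unadjusted), so that value restates the shares and is no independent test. None of the 8 mitochondrial peaks held the repeat. Over all chromosomes, replicates 1 and 2 taken alone gave shares of 16.1% and 14.7%.

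For the GA repeat, GC content of the windows goes with part of the excess, since the odds ratio was 6.19 against windows not matched on GC and 3.98 against GC-matched ones. It does not account for all of it, as the interval of the matched value was 2.72 to 5.76. With both sets limited to promoter windows the odds ratio was 2.08 (11.4% against 5.82%), and its unadjusted interval of 1.01 to 4.03 came close to 1. The mean GC content of these 2 sets also differed (48.4% against 46.5%). The value lay above 1, but with these limits promoter windows in general cannot be set aside as an account of the excess. Reads shared between exact repeat copies would need repeated sequence, yet 0.378% of the 50-base stretches in those windows occurred more than once in the genome, all in 1 window. The check counted exact copies of 50 bases only. Reads shared between shorter or inexact copies were not tested, so that explanation stays open.

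The peak in *ceh-22* is of interest because the transgene carries that gene, and extra copies would raise signal over the whole locus alike. The largest other region within 5 kb of the gene had 23.2% of the peak's pooled signal value, but copies would multiply both alike, so this share leaves extra copies open. A raised background around the gene stays open too. Within 20 kb, but outside the gene, 19 pooled regions lay against a median of 8 in windows elsewhere, at percentile 99.5, with percentiles of 94.7 in replicate 1 and 99.3 in replicate 2. The extent of the transgene and the strain of the control are not given in the sources used here, so a contribution from copy number cannot be told apart from clustered binding.

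The lack of correlation between the replicates' signal values across thresholded peaks was set against a narrower range of signal after selection on the pooled value. Over all 7457 replicate 1 regions with a replicate 2 summit within 200 bp, Spearman's rho was 0.231 (permutation p = 0.000999, the smallest that 1000 permutations can give), as a narrower range would need. The spread of the log signal was not clearly narrower in the thresholded peaks, however. Its SD there was 0.953 times that over all those regions in replicate 1 (95% bootstrap interval 0.844 to 1.07) and 1.17 times in replicate 2 (1.00 to 1.33). Its interquartile range was 0.891 and 0.939 times (0.790 to 1.03 and 0.773 to 1.13). Selection on a value made from both replicates can lower their correlation without narrowing the spread of either. The ratios therefore cannot test the effect of selection, and that explanation stays open. The scale of the signal value is not stated, and these ratios depend on it. Noise in the signal values of single libraries was not tested.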
